A study of Homo sapiens with 8 samples.

How the data were processed

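SHALiPE-seq reads RNA structure from the stops of reverse transcription at nucleotides modified by NAI, with DMSO-treated cells as background. Per the labels' protocols, control and TDP-43 knockdown HEK293T cells were probed in suspension, poly(A) RNA was selected, 500 ng was fragmented to about 300 nt, and reverse transcription ran in a lithium buffer before adapter ligation and PCR. No molecular identifiers are mentioned there. The submitters' processing notes name cutadapt 1.15, Bowtie2 2.3.3.1 and the genome build hg38. How reads were turned into reactivities, how reactivities were scaled, the transcript annotation and any coverage filter are not given in the sources used here.

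The authors deposited 1 table per condition. Per the file headers, each gives for a transcript the maximum, the average and the standard deviation of reactivity, a score per nucleotide whose scale is not stated, and the Gini index, a fraction between 0 and 1. The word combined in the column names was taken to mean that the authors combined the 2 replicates and that the NAI signal was set against DMSO. The knockdown columns carry a prefix that the labels do not explain. The 2 tables list the same 38314 transcripts, and values were used as deposited. All maxima lie at or below 7. No column of per-sample values was present, so replicate agreement, the level of the targeted transcript and read depth were not analysed here. Because the values are scores and fractions without counts or replicates, no count model and no p-value was used.

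The number of positions behind each transcript was recovered from the deposited values. An average over n positions of reactivities with 3 decimals must give a whole number of thousandths when multiplied by n, and the Gini index times n times that sum must also be whole. The smallest n that met both conditions in both tables within the rounding of the deposited digits was taken, and 38312 transcripts had one, with a median of 1051 and a middle 50% of 556 to 2360. In 1000 simulated transcripts the number was exact in 96.1%, and in the other 39 it was a divisor of the true number. As a further check, the sum of squares implied by the standard deviation was whole in 99.5% of control transcripts of 51 to 1499 positions with the population formula. Positions are those that entered the authors' average, which can be fewer than the nucleotides of the transcript.

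For each measure, transcripts higher and lower in knockdown were counted, ties were left out, and the share higher was given with a 95% Clopper-Pearson interval. Medians of differences have percentile intervals from 1000 bootstrap draws over transcripts. In the simulated table of 38314 transcripts with 200 raised and 200 lowered, the share higher was 50%. With ties left out this value follows by construction, so it checks the counting only. Transcripts were divided into 5 groups of 20% by the mean of the average reactivity in both conditions, and into 7 classes by positions. The share of positions that must carry reactivity is the squared average divided by the sum of the squared average and the variance, a lower bound. The median difference of each length class was set among the medians of 10000 random lists of the same size, drawn from the other transcripts. Lists were matched in 10 bins of level for average reactivity. For the Gini index they were matched in 10 bins of its mean over both conditions. In simulation, 3 of 40 lists of 300 transcripts without a shift fell outside the central 95%, and 40 of 40 with a shift of 0.02 lay above it. The simulated shift left the matching level unchanged, whereas in the data a knockdown difference also moves the level. A curve of control average against control coefficient of variation, from medians in 200 bins, served to place each knockdown transcript on a scale of its own. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

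The measures over all transcripts, the rule for named transcripts and the main alternatives were chosen before the data were examined. The level groups, the length classes, the joint directions and the control's curve were chosen after. The rule named, among transcripts of at least 500 positions outside the lowest 25% by level, the 12 largest increases and the 12 largest decreases of average reactivity and the 5 largest of each direction of the Gini index. Because the gene table used here holds no Ensembl identifiers, the transcript identifiers could not be paired with gene names, and 2 identifiers per direction of the average are printed, 1 transcript per gene could not be chosen, and the 19 gene lists fixed in advance were not analysed here. Transcript sequences were not used here, so the planned comparisons of transcripts with a G-quadruplex motif or a UG repeat were not made. Alternatives were a filter on the lowest 25% by level, at least 1000 positions, division of each condition by its median, changes over 10% only, and log2 with a pseudocount of 0.01. Leaving out transcripts at the ceiling, counting identical transcripts once (367 transcripts in 156 sets share all 8 values), the knockdown's own scale and groups by control level were added after the data had been seen, as was the division of transcripts by whether their control Gini index left room for an increase of more than 10%. The knockdown's own scale is a function of the coefficient of variation alone, so it restates evenness and is no separate test of level.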

Results

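RNA structure was probed in HEK293T cells, a human embryonic kidney line, with and without knockdown of TDP-43, an RNA- and DNA-binding protein that regulates splicing and mRNA metabolism and forms aggregates in amyotrophic lateral sclerosis. The series title places the question in the binding of TDP-43 to RNA G-quadruplexes, which are four-stranded folds of guanine-rich RNA. The probe was NAI, a reagent that acylates the 2'-hydroxyl of flexible nucleotides, applied at 100 mM for 15 min at 37 °C, and 5% DMSO served as the unprobed background. The 8 libraries formed 4 groups of 2 replicates, namely control with NAI, control with DMSO, knockdown with NAI and knockdown with DMSO. The values analysed were 1 combined summary per condition for each of 38314 transcripts, giving the average, the standard deviation, the maximum and the Gini index of reactivity along the transcript. The Gini index runs from 0, where reactivity is spread evenly over all positions, to 1, where few positions carry it. No read counts accompany these summaries, so the depth behind each value is unknown, and the combined values have no replicate error.

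On the deposited scale, which is not stated, knockdown of TDP-43 was accompanied by a wider range of average reactivity, with a similar median and a higher mean. The median transcript had an average reactivity of 0.190 in control and 0.185 in knockdown, and the mean over transcripts was 0.199 in control and 0.228 in knockdown, while the middle 50% of transcripts spanned 0.154 to 0.229 in control and 0.136 to 0.293 in knockdown. Average reactivity was higher in knockdown in 18959 transcripts and lower in 19350, a share higher of 49.5% (95% exact binomial interval 48.99 to 49.99). The median difference, knockdown minus control, was -0.0011, with a bootstrap interval over transcripts of -0.0022 to 0.00003. The median difference turned positive in other selections of transcripts, to 0.031 after a filter on the lowest 25% by level and 0.011 without transcripts whose maximum stood at a ceiling of 7. The share higher lay between 51.4% and 64.0% in 4 such selections, so the direction over all transcripts did not hold. Large differences lay mostly on the side of higher reactivity, with 5770 transcripts at least 1.5-fold higher in knockdown and 916 at least 1.5-fold lower. At 2-fold the numbers were 326 higher and 44 lower. Across transcripts the 2 conditions correlated with a Pearson r of 0.858 and a Spearman rho of 0.860, where transcripts are not independent replicates.

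With combined replicates none of these differences could be set against replicate spread, and no p-value was computed. The intervals cover the counting of transcripts only, and they treat transcripts as independent. Isoforms of 1 gene share reads, so the intervals are narrower than they should be.

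**Figure D1:**
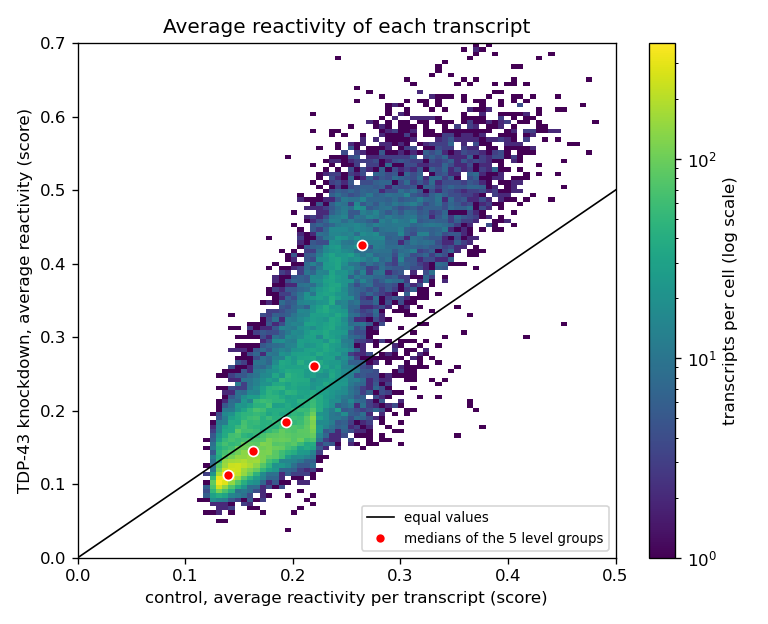
Average reactivity of 38314 transcripts in control (x axis, score) and TDP-43 knockdown (y axis, score), as the number of transcripts per cell on a log colour scale. The black line marks equal values, and the red points are the medians of 5 groups of transcripts by average reactivity, of which the highest 2 lie above the line and the lowest 3 below it.

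The direction of the difference followed the reactivity level of the transcript. Among the 20% of transcripts with the lowest average reactivity over both conditions, the median was 0.140 in control and 0.112 in knockdown, and 3.09% of transcripts were higher in knockdown (interval 2.72 to 3.51). Among the 20% with the highest level, the median was 0.264 in control and 0.426 in knockdown, and 99.3% were higher in knockdown (interval 99.1 to 99.5). The share higher in the 3 groups between was 26.7%, 39.3% and 79.0% in order of level. Transcripts at the ceiling of 7 in either condition numbered 1810, 2619 and 377 in these groups, against 250 in the lowest and 23 in the highest. The shares of the groups between therefore cannot be read as an effect of level alone. The median difference ran from -0.029 in the lowest group to 0.153 in the highest, a median ratio of knockdown over control of 0.793 and 1.57. Grouping by the mean of both conditions favours this order, since knockdown values vary more. With groups by control level alone the shares higher were 19.8% in the lowest and 88.0% in the highest group. In control the average itself followed closely from the coefficient of variation, so this grouping does not separate level from evenness. With groups formed anew after the filter on low values, 29.7% of the lowest group were higher. On a scale of the knockdown's own, read from the coefficient of variation alone, 62.0%, 41.5%, 34.1%, 53.8% and 86.2% of the 5 groups in order of level were higher. The curve behind that scale does not fall below 0.132, while levels in the lowest group ran from 0.092 to 0.140. The 62.0% of that group is thus in part set by the curve and cannot be read as a reversal. That reading restates evenness and holds no separate information on level.

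The Gini index, which does not depend on the scale of reactivity except through a ceiling of 7 on single values, was higher in knockdown in 63.8% of transcripts (interval 63.3 to 64.3). Its median was 0.837 in control and 0.855 in knockdown, with a median difference of 0.0072. Its mean over transcripts went the other way, at 0.823 in control and 0.816 in knockdown. After the filter on low values the share higher was 53.8% and the median difference 0.0030. With the medians of both conditions set equal, 27.0% were higher. Those medians lay further apart than the median difference within transcripts, so this division takes off more than the typical difference. The index divided by level in the opposite sense to the average. In the lowest 20% by level the median Gini index was 0.918 in control and 0.933 in knockdown, and 94.8% of transcripts were higher in knockdown. In the highest 20% it was 0.690 in control and 0.610 in knockdown, and 12.4% were higher. With groups by control level alone these shares were 91.2% in the lowest and 25.4% in the highest group. The index cannot exceed 1, and the 10884 transcripts with a control value of at least 0.905 had no room for an increase of more than 10%. Of these, 93.0% were higher in knockdown, against 52.3% of the other 27430. Of the 5032 transcripts whose Gini index differed by more than 10% of its mean, all from those 27430, 4.99% were higher in knockdown.

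Average and evenness differed together in most transcripts. Reactivity was lower on average and more uneven in knockdown in 17319 transcripts, 45.2% of those that differed in both measures. It was higher on average and more even in 11831 transcripts, or 30.9%, and these had the highest average in control, with a median of 0.236. A further 7128 transcripts, 18.6%, were higher on average and more uneven, and these were the longest, with a median of 2421 positions. The remaining 2031 transcripts, 5.30%, were lower on average and more even, with a median of 437 positions. The share of positions that must carry reactivity to give the observed average and standard deviation had a median of 17.7% in control and 15.8% in knockdown, and it was higher in knockdown in 36.4% of transcripts.

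**Figure D2:**
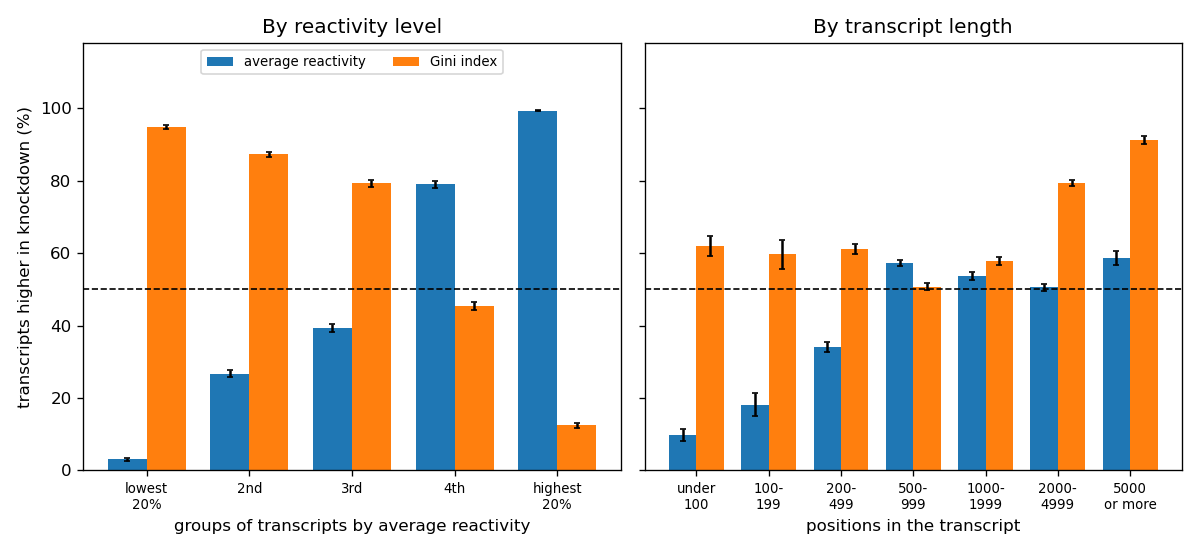
Share of transcripts with a higher value in TDP-43 knockdown than in control (y axis, percent) for average reactivity (blue) and the Gini index (orange), in 5 groups by average reactivity (left) and 7 classes by number of positions (right). Bars start at 0, error bars are 95% exact binomial intervals over transcripts, and the dashed line marks 50%; the 2 measures move in opposite senses from the lowest to the highest level.

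Single-position extremes and spread were both higher in knockdown in more transcripts than not. The maximum reactivity had a median of 2.32 in control and 2.59 in knockdown, and it was higher in knockdown in 67.3% of the transcripts whose maxima differed (interval 66.8 to 67.7). Both tables stop at a maximum of 7, reached by 4195 control transcripts (10.9%) and 4820 knockdown transcripts (12.6%), and 3936 transcripts reached it in both. The standard deviation along the transcript had a median of 0.381 in control and 0.451 in knockdown and was higher in knockdown in 55.1% of transcripts (interval 54.6 to 55.6). The middle 50% of control transcripts had standard deviations of 0.368 to 0.438, against 0.379 to 0.539 in knockdown. The scale of the 2 tables is not stated. With the medians of both conditions set equal, 39.9% of maxima and 34.4% of standard deviations were higher in knockdown. The median difference within transcripts was 0.137 for the maximum and 0.015 for the standard deviation, less than the distance between the medians. Division by the medians therefore takes off more than the typical difference.

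The control summaries were tied to each other more closely than those of the knockdown. Once the coefficient of variation of a control transcript was known, its average followed with an SD of 0.066 on the log2 scale, and 91.9% of control transcripts lay within 0.1 of that curve. Of the knockdown transcripts, 16.4% lay within 0.1 of the same curve, with an SD of 0.395. Across transcripts the log2 ratio of knockdown over control average had an SD of 0.426. Its part given by the distance of knockdown averages from the curve had an SD of 0.395, and the remaining part, read from evenness, 0.208. Averages of the 2 conditions are compared here on the scale as deposited, so the wider range in knockdown cannot be separated from how the tables were scaled.

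**Figure D3:**
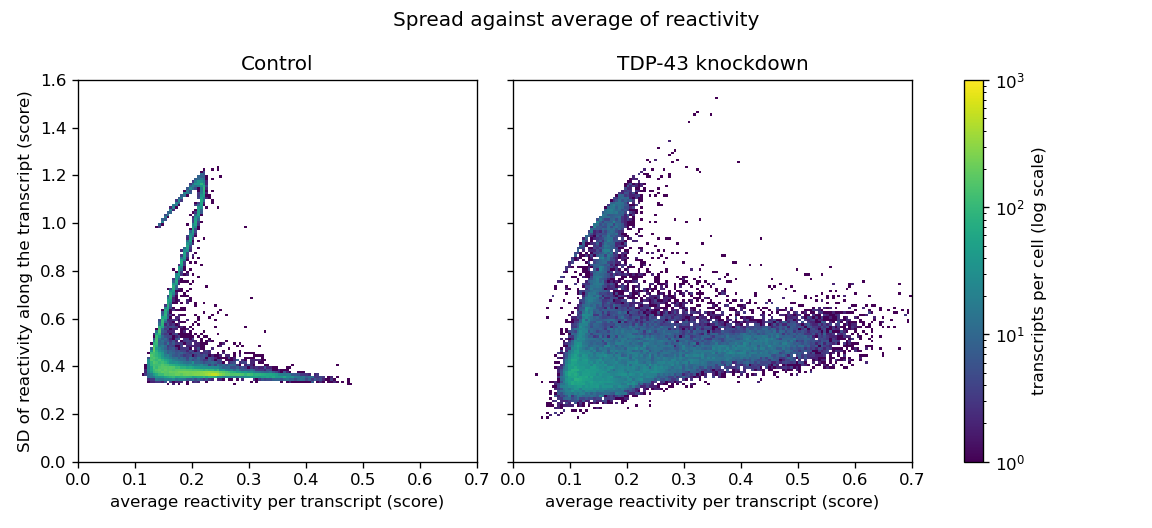
Standard deviation of reactivity along the transcript (y axis, score) against average reactivity (x axis, score) in control (left) and TDP-43 knockdown (right), as transcripts per cell on a log colour scale. Control transcripts follow a narrow curve, while knockdown transcripts are spread around it and reach averages of 0.696 against 0.479 in control.

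Short transcripts had lower average reactivity in knockdown. The median was 0.195 in control and 0.152 in knockdown for the 1257 transcripts of under 100 positions, of which 9.71% were higher in knockdown (interval 8.13 to 11.5). The share higher was 17.96% of the 608 transcripts of 100 to 199 positions and 34.1% of the 5522 transcripts of 200 to 499 positions. It was 57.3% among 11244 transcripts of 500 to 999 positions, 53.7% among 7863 of 1000 to 1999, 50.6% among 9324 of 2000 to 4999, and 58.7% among 2494 of 5000 or more. On the knockdown's own scale, which restates evenness, 3 classes changed side, with 53.9% higher at 200 to 499 positions, 48.6% at 2000 to 4999 and 35.5% at 5000 or more. The Gini index set the longest transcripts apart without a steady rise with length. It was higher in knockdown in 62.1%, 59.6% and 61.2% of transcripts in the 3 shortest classes in order of length, 50.8% of those of 500 to 999 positions, 57.8% of those of 1000 to 1999, 79.4% of those of 2000 to 4999 and 91.2% of those of 5000 or more, where its median was 0.895 in control and 0.915 in knockdown. In average reactivity each of the 7 length classes lay outside the central 95% of random lists matched on level. For the Gini index the lists were matched on the mean index of both conditions, not on level. Against those lists, transcripts under 100 positions lay inside the central 95%, at percentile 55.8. The other classes lay outside it. Classes from 100 to 1999 positions were below it, at percentiles of 0 to 0.01, and those of 2000 or more were above it, at percentile 100. The median difference in average reactivity under 200 positions was -0.038, against -0.014 to -0.010 in the central 95% of 10000 lists, and at 5000 positions or more it was 0.011, against -0.019 to -0.016.

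The transcripts with the largest differences were named by their Ensembl identifiers, which the tables do not pair with genes. Among 23536 transcripts of at least 500 positions and not in the lowest 25% by level, ENST00000331821.7 had the largest increase, from an average reactivity of 0.245 in control to 0.679 in knockdown, 2.77-fold higher, with a Gini index of 0.720 in control and 0.594 in knockdown over 817 positions. ENST00000411892.5 followed, with an average of 0.218 in control and 0.602 in knockdown over 564 positions. The largest decrease was in ENST00000409190.8, with an average of 0.217 in control and 0.087 in knockdown, 2.49-fold lower, and a Gini index of 0.967 and 0.988 over 3483 positions. ENST00000525617.2 had an average of 0.205 in control and 0.090 in knockdown over 594 positions. All 12 of the largest increases had a lower Gini index in knockdown, and none of the 12 largest decreases did. All 12 of the largest decreases had control maxima at the ceiling of 7, and none of the 12 largest increases had. The size of these differences rests on the deposited scale, which is not stated. On the knockdown's own scale, which restates evenness, the 2 increases shrank to 0.083 and 0.093 and the 2 decreases to -0.057 and -0.045.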

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

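The small majority of transcripts with lower average reactivity in knockdown (49.5% higher) did not hold. The share higher was 64.0% after the filter on low values, 52.9% with at least 1000 positions, 51.8% with each condition divided by its median, 51.4% for changes over 10% only, 54.3% without transcripts at the ceiling and 55.5% with the knockdown on its own scale. The Gini index (63.8% higher) moved to 53.8% after the filter on low values, 72.2% with at least 1000 positions and 58.9% without transcripts at the ceiling, and turned to 27.0% with each condition divided by its median and to 4.99% for changes over 10% only. The standard deviation (55.1%) moved to 68.0%, 60.8%, 59.8% and 61.9% with the filter, with at least 1000 positions, without the ceiling and for changes over 10% only, and turned to 34.4% with each condition divided by its median. The maximum (67.3%) moved to 72.3%, 78.1% and 74.1% with the filter, with at least 1000 positions and for changes over 10% only, and turned to 39.9% with division by the median. The filter, the limit on positions and the limit on size change which transcripts are counted. Division by the median sets the medians of both conditions equal. In all 4 measures these medians lay further apart than the median difference within transcripts. A turn of side with this setting can therefore follow from the divisor. The Gini index cannot exceed 1, so the limit of 10% leaves out increases from high values. Among the 27430 transcripts with room for such an increase, 52.3% were higher, against 4.99% of the 5032 of these that changed by over 10%. All 5032 lay in this set, where room could be slight, so the 4.99% is no separate check. Counting identical transcripts once moved none of the 4 shares beyond its interval. The log2 scale keeps the order of values and so cannot change a share. Of 64 further alternative values, for the level groups, transcripts under 200 positions, medians and named transcripts, 6 changed side. The median difference in average reactivity, -0.0011 with an interval that holds 0, became 0.031 with the filter, 0.0065 with at least 1000 positions, 0.011 without the ceiling, 0.0035 with division by the median and 0.0032 on the knockdown's own scale. The share higher in the lowest 20% by level went from 3.09% to 62.0% on the knockdown's own scale, which is read from the coefficient of variation alone and so restates evenness. The curve behind that scale does not fall below 0.132, so this turn is in part set in advance. On that scale the named differences kept their direction but shrank, from 0.434 and 0.385 to 0.083 and 0.093 in the 2 increases and from -0.129 and -0.115 to -0.057 and -0.045 in the 2 decreases. No paired analysis was possible because each table holds 1 combined value per transcript and condition, and for the same reason no replicate could be left out. Alternatives that need gene names or sequences were not run. Depth is unknown, so no limit from counting error can be given for any transcript.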

Other observations

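The tests of the level groups, of scale and of shared depth were chosen after the result was seen. That of level in short transcripts was written before its result, but on a length class chosen after the data were examined. Short transcripts formed sharp peaks in length. Of those under 200 positions, 263 had exactly 87 positions and 162 had exactly 82, and the next most common number, 99, held 49. Separately, 5 transcripts had identical values of all 4 measures in control and knockdown, and all 5 stood at the ceiling of 7.

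On the deposited scale, reactivity in knockdown was lower and more uneven in transcripts with a low average over both conditions. It was higher and more even in those with a high one. In control the average followed closely from the coefficient of variation, so groups by level mix level and evenness. The reverse did not hold, since similar control averages came with different Gini indices. ENST00000411892.5, with a control average of 0.218 and a Gini index of 0.749, was higher in knockdown. ENST00000409190.8, at 0.217 and 0.967, was lower, though both were named for their large differences. Evenness was not compared at equal level, so a dependence on level was not separated from one on evenness. Knockdown averages scattered around a curve of their own with an SD of 0.287 on the log2 scale, against 0.066 in control. The knockdown table thus does not look scaled transcript by transcript on its own values. A factor shared by all its transcripts would not show in this comparison, so how it was scaled stays unknown. A candidate explanation for the wider range of averages is that knockdown reactivities were divided by factors taken from control; whether the averages differ beyond such factors cannot be told apart, because an own scale read from evenness (86.2% of the highest and 62.0% of the lowest 20% by level higher in knockdown) holds no level of its own. Scale alone does not account for the split in evenness, because the Gini index does not depend on scale and was higher in 94.8% of the lowest and 12.4% of the highest 20% by level, and in 91.2% and 25.4% with groups by control level. Changes of depth or coverage, shared by all transcripts or not, and an effect of TDP-43 knockdown remain open, since the authors' steps from reads to reactivity are not known and there is 1 combined value per condition.

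The lower average reactivity of transcripts under 200 positions in knockdown might reflect their level. Their median difference lay at percentile 0 of the 10000 lists matched on level, below every list, which argues against this for level as the mean of both conditions. That level includes the knockdown value, and the class was chosen after the data were examined. A difference of scale stays open, since the own-scale reading, with 67.0% of them lower in knockdown, restates evenness. Recovery of short transcripts by fragmentation, size selection and poly(A) selection could differ between the conditions and was not tested, nor was an effect of TDP-43 knockdown.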
